A study of Caenorhabditis elegans with 2 samples.

How the data were processed

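Chromatin bound by eGFP-tagged BLMP-1 was measured by ChIP-seq in whole L1 larvae of mixed sex in 2 samples, biological replicates 1 and 2 of 1 group per the labels. The labels name a possible control, whose libraries were not analysed here. Per the labels, the assemblies are ce10 and ce11 and the fragment size range was 150 to 350. Peaks were called against a control, per the deposited file listings. The extraction protocol, aligner, peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited peak lists are of narrowPeak type: per the deposited file listings, the authors called peaks and background on each replicate, and on both replicates together, as input for an IDR analysis, which gave the optimal list. The peak signal is the deposited value of the authors' caller and its scale is not given, so it was used only to rank, describe and filter peaks within a list. The deposited −log10 q-value was described and not tested: 38.9% of the optimal peaks share its maximum of 3.83. No read counts were used and depth is unknown, so depth-based precision cannot be given per sample. The replicates' lists held 27310 and 30000 peaks.

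Summits were read from the lists as start plus offset and given 1-based. One genome build, ce11 (WBcel235), was used with gene models of Ensembl release 115. The ce10 lists served as an alternative for values that need no annotation. MicroRNA symbols came from RefSeq records of the same assembly, which named 260 of 261 genes. Peak matches used summits within 100 bp and the N strongest peaks of each replicate, with N = 8751. Expectations came from 1000 circular shifts of at least 10000 bp. Summits were set against protein-coding transcript starts at 500 bp. Genes were bound when a summit lay from 1500 bp upstream to 500 bp downstream of a start. In the alternative with the nearest start only, a summit counted for the gene of its nearest start, up to 3000 bp away on either side. The share of bound genes in each of 32 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, and a list of microRNAs was given as a value. Peak strength was compared with 100000 resamples for lists with at least 5 bound genes. Adjusted p-values are Benjamini-Hochberg values and calls were made at 0.05. The motif AAAGTGAAA was counted on both strands with at most 1 mismatch within 75 bp of summits and in flanks 500 bp away. Flank shares are means over both flanks, and the exact tests of the motif against flanks used the right flank alone. Peaks near blmp-1 and unc-119 were counted within 20 kb. Intervals are 95% Clopper-Pearson intervals.

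The groups, tests, gene lists, motif and alternatives were fixed before the data were examined. Genes named are blmp-1 and unc-119, every heterochronic gene, the genes of the 10 strongest promoter peaks found in both replicates, and the 3 bound genes with the strongest peaks of each other list, with equal signals ordered by position. The lists were heterochronic genes, molting genes, furrow collagens, other collagens with a mutant phenotype, numbered collagens, cuticlins, seam and hypodermis genes, epidermal antimicrobial peptides, patched-related and hedgehog-related genes, astacins, nuclear hormone receptors, ceh homeobox genes, the Wnt, Sma/Mab, and dauer and insulin pathways, distal tip cell migration genes, markers of intestine, muscle, pharynx, neurons, neuron identity and germline, chemoreceptors, ribosomal proteins, proteasome subunits, histones, major sperm proteins, C-type lectins, F-box A genes, insulin-like peptides, cytochrome P450 and microRNAs. Several genes sit in more than 1 list, such as nhr-23 and nhr-25.

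The alternatives were the ce10 lists, the stronger 4375 peaks, peaks matched in both replicates, removal of 333 peaks within 1000 bp of tRNA, rRNA, snRNA or snoRNA genes, each replicate left out by use of the other's 8751 strongest peaks, other distances and windows, the nearest start only, rotation along gene order with 10000 rotations, upstream length as a covariate, and other motif settings and controls. The text listings beside the lists were not used for values. On simulated data the list test found 98.5% of lists whose odds of binding were raised in 20 draws over 19973 genes, and called 0.938% of unchanged lists. Small lists such as the furrow collagens were not raised. The simulated rise exceeded that of called lists such as numbered collagens (log2 odds ratio 0.892) and nuclear hormone receptors (0.706), so the share found does not hold for them. Simulated genes were bound independently, so the share of false calls does not cover clustered families or shared peaks. The overlap gave 60.7% where 60% of 8000 summits were shared. The count of exact motif matches in random sequence gave 30% where 30% of 2000 summits held a planted motif. It does not check the count with at most 1 mismatch in the real genome. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.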

Results

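BLMP-1, a zinc-finger transcription factor and the C. elegans homolog of mammalian Blimp-1 (PRDM1), was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole larvae of the L1 stage, the first of the larval stages. The worms were of strain OP109, which carries an eGFP-tagged blmp-1 transgene (wgIs109) in an unc-119(ed3) background. The group held 2 biological replicates, numbered 1 and 2 in the labels, and no other condition. The measurements were the authors' lists of peaks on genome build ce11: 8751 optimal peaks that passed their irreproducible discovery rate (IDR) filter, 30000 peaks called on both replicates together, and 27310 and 30000 peaks called on replicates 1 and 2 alone. The optimal peaks were exactly the 8751 strongest of the pooled list and covered 2484 kb, with a most frequent width of 336 bp. Their signal, a value from the authors whose scale is not given in the sources used here, ran from 62.0 to 4255 with a median of 147. It was used only to describe and rank peaks within a list. Read depth was unknown, so no interval below rests on it: intervals on shares of peaks or genes are exact binomial ones and cover counting error only. Tests across peaks or genes describe these pooled peaks. They do not measure the spread between animals.

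The replicates placed most of their strong peaks at the same sites. Of the 8751 strongest peaks of replicate 1, 6598 (75.4%) had a summit within 100 bp of one of the 8751 strongest of replicate 2. Circular shifts of replicate 2 along the chromosomes gave 1.79% on average and at most 2.32% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The site of the strongest optimal peak, upstream of the bZIP factor gene atf-2, ranked 18 in replicate 1 and 1 in replicate 2, and that of the glycerol-3-phosphate dehydrogenase gene gpdh-3 ranked 9 and 23. Of the optimal peaks, 6581 (75.2%) were matched among the strongest of both replicates, 1444 (16.5%) in replicate 2 only, 638 (7.29%) in replicate 1 only and 88 (1.01%) in neither. The signals of the 2 replicates at 7907 optimal peaks present in both lists had a Spearman's rho of 0.693, taken across peaks, which are not independent replicates.

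BLMP-1 peaks lay mostly upstream of protein-coding transcripts and avoided coding sequence. In total 3579 of 8751 summits (40.9%) lay within 500 bp of a protein-coding transcript start, against 22.8% on average and at most 24.2% in circular shifts (ratio 1.79, one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The nearest start lay downstream of the summit for 73.8% of peaks, and the median distance was 835 bp. The 200 bp just upstream of a start held 20.9% of summits and the 200 bp just downstream 4.11%. Intergenic sequence held 61.3% of summits and 34.7% of the genome, and introns held 24.4% and 32.7%. Coding exons held 2.32% of summits and 24.6% of the genome, 5′ UTRs 3.74% and 1.43%, 3′ UTRs 1.73% and 3.32%, and exons of other gene types 6.57% and 3.24%.

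**Figure D1:**
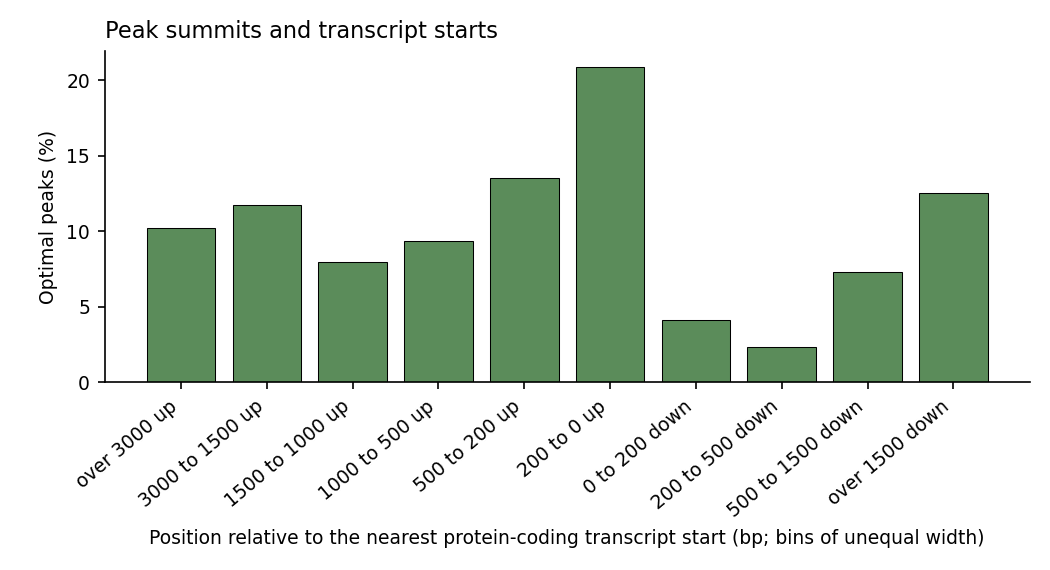
Share of the 8751 optimal peaks (bars, %) by the position of the summit relative to the nearest protein-coding transcript start, in bp, upstream to the left and in bins of unequal width. The bin from 200 bp upstream to the start holds 20.9% of peaks and the bin to 200 bp downstream 4.11%.

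With a gene called bound when a summit lay from 1500 bp upstream to 500 bp downstream of a transcript start, 5476 of 19973 protein-coding genes (27.4%) were bound. Every annotated start of a gene, internal ones included, had its own window. Genes with many starts, such as lin-42 with 5 and nhr-23 with 6, thus had more room for a summit. No list comparison below adjusted for the number of starts. The heterochronic genes, which time larval cell fates, were bound more often than other genes, in 15 of 22 cases (68.2%, exact 95% interval 45.1 to 86.1%; Fisher's exact test, adjusted p = 2.8e-04). Among the strongest was kin-20, a casein kinase gene, with 4 peaks. Its best (rank 87, signal 1293) lay in an intron at chromosome X 15274888 to 15275319 and held an exact AAAGTGAAA. The nuclear hormone receptor gene nhr-85 ranked 92 (signal 1273, I 13062569 to 13063074, intergenic, 731 bp upstream). The gene of the RNA-binding protein LIN-41 ranked 129 (signal 1113, I 9343741 to 9344107, intergenic, 1486 bp upstream, near the 1500 bp limit of the window). The Period homolog gene lin-42 had 6 peaks, the best at rank 131 (signal 1106, II 1241400 to 1241701, in its own intron), and nhr-25 had 2, the best at rank 182 (signal 966, X 13008890 to 13009256). The nuclear hormone receptor gene nhr-23 had 5 peaks (rank 897, I 7217157 to 7217471, intron).

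The strongest peaks of the other bound heterochronic genes ranked from 2064 to 8436. The gene lin-14 had 3 peaks (best rank 2180, X 11465199 to 11465534, intergenic, 193 bp upstream) and lin-28, which encodes an RNA-binding protein, had 4 (best rank 3136, I 8409690 to 8410025, in its 5′ UTR). The zinc-finger factor gene lin-29 ranked 2329 (II 11935360 to 11935576, intergenic), the microRNA gene lin-4 2931 (II 5901855 to 5902190, 231 bp upstream) and the microRNA gene let-7 4954 (X 14745282 to 14745617, intergenic, 129 bp upstream). The hunchback homolog gene hbl-1 ranked 5523 (X 5820795 to 5821130, intergenic, 1179 bp upstream). The gene lin-46 ranked 8102 (V 12967774 to 12968109, 913 bp upstream, in the 5′ UTR of the neighbouring gene R186.8). The F-box gene dre-1 ranked 8436 (V 6538446 to 6538781, intron) and the Argonaute gene alg-1 2064 (X 13950449 to 13950809). For lin-4, let-7, lin-46, dre-1 and alg-1 replicate 1's list had no summit within 100 bp of the peak. No optimal peak lay in the windows of mir-48, mir-84 and mir-241 (microRNA genes of the let-7 family), daf-12, sea-2, lep-2 and alg-2. The call held under all 10 alternatives tried, each left-out replicate included (adjusted p from 1.4e-05 to 0.0131).

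The strongest promoter peaks belonged to genes of several kinds. The peak of atf-2 had the highest signal (4255, II 8750906 to 8751479, 826 bp upstream, in exons of the neighbouring non-coding genes K08F8.10 and K08F8.8) and held an exact motif match. Below it came K08F9.4 (rank 4, V 15143853 to 15144157, in the 3′ UTR of the neighbouring gene K08F9.3), the lipocalin-related gene lpr-4 (rank 5, X 11064781 to 11065241), W03F8.4 (rank 6, IV 5183736 to 5184123), edc-4 (rank 8, I 3349847 to 3350209) and noah-2, which encodes an apical extracellular matrix protein (rank 9, IV 14089572 to 14090204). They were followed by gpdh-3 (rank 12, I 7563012 to 7563369), R07E3.6 (rank 14, X 10317461 to 10317953, 5′ UTR), din-1, which encodes a DAF-12-interacting protein (rank 17, II 11617725 to 11618059, intron), and the furrow collagen gene dpy-8 (rank 20, X 5150416 to 5150817, intergenic, 164 bp upstream). All 10 had a summit among the 8751 strongest peaks of each replicate, by the rule that chose them. Of these peaks, those of noah-2 and dpy-8 held no AAAGTGAAA with at most 1 mismatch within 75 bp of the summit.

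Genes of the cuticle and of the molts were bound more often than other genes. All 6 furrow collagen genes were bound (100%, exact 95% interval from 54.1%, adjusted exact p = 0.00113): besides dpy-8, dpy-10 ranked 49 (signal 1566, II 6712229 to 6712930) and dpy-2 114 (signal 1164, II 6713709 to 6714310). Molting genes were bound in 18 of 24 cases (75%, 53.3 to 90.2%, adjusted exact p = 9.0e-06), among them noah-2, nhr-25 and nhr-23. Of the 156 numbered collagen genes 64 were bound (41%, 33.2 to 49.2%, adjusted exact p = 8.1e-04), led by col-149 (rank 105), col-80 (276) and col-88 (294). Patched-related genes, whose products resemble sterol-sensing membrane proteins, were bound in 18 of 26 cases (69.2%, 48.2 to 85.7%, adjusted exact p = 4.9e-05), led by ptr-10 (rank 50, I 5661879 to 5662241), ptr-1 (479) and ptr-2 (485). These calls were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 32 lists. All 4 held under the 10 alternatives, with adjusted p at most 0.00576 for furrow collagens, 0.00959 for molting genes, 0.0138 for numbered collagens and 0.0236 for patched-related genes.

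Other collagens with a mutant phenotype, cuticlins, seam and hypodermis genes and epidermal antimicrobial peptides were also bound more often, with calls that depended on the processing. Other collagen genes with a mutant phenotype were bound in 9 of 14 cases (64.3%, 35.1 to 87.2%, adjusted exact p = 0.00914), led by lon-3 (rank 249), rol-6 (982) and dpy-5 (3478). Cuticlin genes were bound in 17 of 35 cases (48.6%, 31.4 to 66.0%, adjusted exact p = 0.0119), led by cutl-28 (rank 203), cutl-1 (314) and cutl-2 (1380). Both calls ended without replicate 2, where 5 of the 14 collagens were bound, with the stronger 4375 peaks, with peaks supported in both replicates and in a window of 500 bp on each side. Their adjusted p over 10 alternatives ran from 3.8e-04 to 0.672 for the collagens and from 6.5e-04 to 0.550 for the cuticlins. Seam and hypodermis genes were bound in 13 of 22 cases (59.1%, 36.4 to 79.3%, adjusted exact p = 0.00608), among them che-14 (rank 70, I 5746421 to 5746778) and grh-1 (898), which encodes a Grainyhead factor. This call ended in the 500 bp window (adjusted p over 10 alternatives from 8.8e-05 to 0.0913). Epidermal antimicrobial peptide genes were bound in 11 of 19 cases (57.9%, 33.5 to 79.7%, adjusted exact p = 0.0119). Neighbours nlp-31 and nlp-34 share the peak at V 3979861 to 3980128 (rank 919), and nlp-29 ranked 1112. Their call ended with the stronger 4375 peaks and under rotation along gene order (adjusted p over 10 alternatives from 0.00502 to 0.338).

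The Sma/Mab pathway, a TGF-β branch that sets body size, had 7 of 10 genes bound (70.0%, 34.8 to 93.3%, adjusted exact p = 0.0109). Its Smad genes sma-3 and sma-2 ranked 368 and 1354, and the Schnurri homolog gene sma-9 ranked 1143. That call ended in the 3000 bp window (adjusted p over 10 alternatives from 0.00497 to 0.0560). Nuclear hormone receptor genes were bound in 102 of 269 cases (37.9%, 32.1 to 44.0%, adjusted exact p = 6.0e-04), led by nhr-85, nhr-135 (rank 106) and nhr-25, and the call ended with the stronger 4375 peaks (adjusted p over 10 alternatives from 2.0e-06 to 0.338). Wnt pathway genes were bound in 11 of 23 cases (47.8%, 26.8 to 69.4%, adjusted exact p = 0.0513), which did not pass the threshold. Among them the Dishevelled gene mig-5 ranked 707, apr-1 (APC) 1573 and lit-1 2634. The list passed with the nearest start only, in the 3000 bp window and without peaks near small RNA genes (adjusted p over 10 alternatives from 0.00770 to 0.905).

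Lists not called were the distal tip cell migration genes with 6 of 15 bound (adjusted exact p = 0.334; the netrin receptor gene unc-40 ranked 1734, the ADAMTS protease gene gon-1 3490) and the hedgehog-related genes with 18 of 59 (adjusted exact p = 0.621; hog-1 416, wrt-1 558, wrt-10 796). The dauer and insulin pathway genes had 4 of 18 bound (adjusted exact p = 0.795; daf-14 ranked 369, akt-2 803 and the insulin receptor gene daf-2 1238). Cytochrome P450 genes had 19 of 74 (adjusted exact p = 0.795; cyp-23A1 1141, cyp-33C4 1710, cyp-13A2 2126) and astacin metalloprotease genes 7 of 37 (adjusted exact p = 0.338; nas-13 1257, nas-36 3224, nas-37 3686). Without replicate 1 the dauer and insulin list had 7 of 18 bound (38.9%) and without replicate 2 it had 6 (33.3%), both above the share of other genes and neither called. Without replicate 2 the cytochrome P450 genes had 23 bound (31.1%), also above other genes and not called, and the astacins 4. MicroRNA genes, given as a value with no test, were bound in 78 of 257 cases (30.4%, 24.8 to 36.4%), and in 67 (26.1%) without replicate 2, just below protein-coding genes. They were led by mir-45 (rank 93, II 11881021 to 11881405), mir-47 (296) and mir-354, whose peak at rank 355 is also that of rps-20.

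Ribosomal protein and proteasome genes were bound more often than other genes. Of 77 ribosomal protein genes 68 were bound (88.3%, exact 95% interval 79.0 to 94.5%, adjusted exact p = 7.0e-28), led by rpl-3 (rank 209, III 3867457 to 3867702, intergenic), rps-20 (355, I 14469212 to 14469461, intergenic) and rpl-35 (491, III 7854582 to 7854815, intergenic). Of 33 proteasome subunit genes 28 were bound (84.8%, 68.1 to 94.9%, adjusted exact p = 7.2e-11), led by rpn-9 (rank 815), rpt-2 (1268) and rpn-3 (1329). Both calls held under all 10 alternatives (adjusted p at most 9.1e-04). With each summit given to the nearest start only, up to 3000 bp away, 40 ribosomal protein genes (51.9%) and 18 proteasome genes (54.5%) were bound, against 22 of 24 molting genes (91.7%). That setting changes reach as well as assignment, so its counts can rise or fall against the main window. Without peaks near small RNA genes, 54 ribosomal protein genes (70.1%) and 26 proteasome genes (78.8%) were bound, and the log2 odds ratio of the ribosomal list was 2.70 in place of 4.27.

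Neuron identity factor, chemoreceptor, major sperm protein, C-type lectin and F-box A genes were bound less often than other genes. None of 18 transcription factor genes of neuron identity was bound (upper exact limit 18.5%, adjusted exact p = 0.0109). This call ended with the stronger 4375 peaks, in the 500 bp window and with the nearest start only (adjusted p over 10 alternatives from 0.00156 to 0.192). Chemoreceptor genes were bound in 34 of 1308 cases (2.60%, 1.81 to 3.61%, adjusted exact p = 3.0e-134), led by srg-26 (rank 589), srh-17 (821) and srh-46 (948). None of 31 major sperm protein genes was bound (upper exact limit 11.2%, adjusted exact p = 2.6e-04). C-type lectin genes were bound in 9 of 240 cases (3.75%, adjusted exact p = 6.1e-21; clec-180 ranked 1490, clec-124 1729, clec-1 2254) and F-box A genes in 12 of 170 (7.06%, adjusted exact p = 1.9e-10; fbxa-90 3095, fbxa-145 4219, fbxa-72 4433). The families are clustered along the genome, and chemoreceptors, lectins, F-box A and sperm protein genes stayed lower under all 10 alternatives, rotation along gene order included (adjusted p at most 9.1e-04, 9.1e-04, 0.00400 and 0.0256).

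Insulin-like peptide genes (3 of 38, 7.89%, adjusted exact p = 0.0109; ins-39 ranked 4759, ins-4 6782, ins-33 7948), ceh homeobox genes (7 of 63, 11.1%, adjusted exact p = 0.00608) and histone genes (11 of 72, 15.3%, adjusted exact p = 0.0358) were also lower. Among the bound homeobox genes were ceh-20, a Pbx homolog (rank 683), ceh-38 (1232) and ceh-58 (4265). The histone genes were led by his-37 (rank 356) and by his-67 and his-68, which share a peak (1287). Without replicate 2, 2 insulin-like genes were bound and the call held. It ended with the nearest start only (adjusted p over 10 alternatives from 0.00409 to 0.0592). The homeobox call ended with the nearest start only and with the stronger 4375 peaks (0.00327 to 0.244). The histone call ended with the stronger 4375 peaks, in the 500 bp window and under rotation (0.00332 to 0.367).

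None of the lists of markers of the other tissues of a larva was called. Their shares lay below that of all genes, but not for pan-neuronal markers without replicate 2 or with the stronger 4375 peaks. Intestine markers had 1 of 16 bound (6.25%, 0.158 to 30.2%, adjusted exact p = 0.122), the vitellogenin gene vit-2 (rank 1184). Body wall muscle markers had 2 of 18 (11.1%, 1.38 to 34.7%, adjusted exact p = 0.245), unc-112 (4329) and act-4 (8254), and pharynx markers 2 of 12 (16.7%, 2.09 to 48.4%, adjusted exact p = 0.607), peb-1 (798) and eat-20 (6205). Pan-neuronal markers had 3 of 17 (17.6%, 3.8 to 43.4%, adjusted exact p = 0.625), unc-33 (174), the synaptobrevin gene snb-1 (1125) and ric-19 (3659). Germline genes had 4 of 22 (18.2%, 5.19 to 40.3%, adjusted exact p = 0.561), among them the Notch receptor gene glp-1 (2786), gld-2 (3256) and syp-2 (7729). Without replicate 2, 5 pan-neuronal markers (29.4%), 2 germline genes, 2 intestine markers and no muscle marker were bound, and without replicate 1, 1 pharynx marker was bound. Muscle markers and astacins passed as lower without replicate 2 and with peaks supported in both replicates, the intestine markers passed as lower with upstream length as a covariate, and the distal tip cell genes passed as higher with the nearest start only. Over 10 alternatives the adjusted p ran from 0.0118 to 1.00 for muscle, 0.0182 to 0.840 for astacins, 0.0416 to 0.670 for intestine and 0.0292 to 0.892 for the distal tip cell. In all, 13 of 32 lists were called higher and 8 lower, of which 5 were lower with the stronger 4375 peaks and 5 with the nearest start only.

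**Figure D2:**
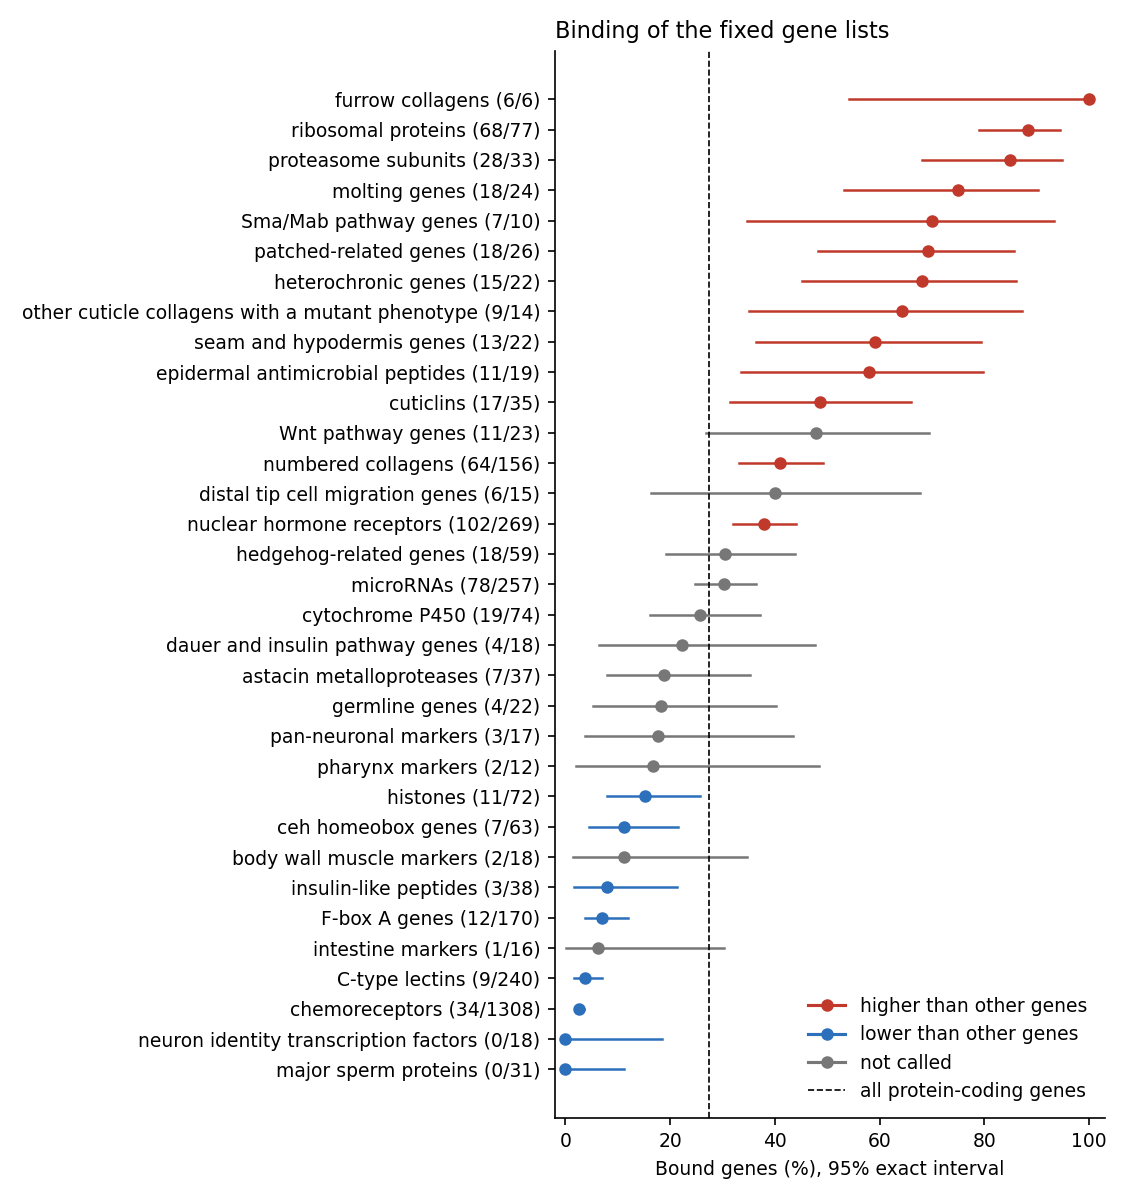
Share of bound genes (%) in each of the 33 fixed lists, as points with 95% exact binomial intervals and bound over listed genes in brackets; colours mark the call and the dashed line is the 27.4% of all protein-coding genes. The furrow collagens (6 of 6), ribosomal proteins (68 of 77) and proteasome subunits (28 of 33) stand at the top, and the chemoreceptors (34 of 1308), neuron identity factors (0 of 18) and major sperm proteins (0 of 31) at the bottom.

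Among bound genes, furrow collagens and ribosomal proteins had the strongest peaks in their windows. The strongest peaks of the 6 furrow collagen genes had a median percentile of 98.6 within the optimal list, against 55.4 for other bound genes. Those of the 68 ribosomal protein genes had a median of 78.4 against 55. For both lists the permutation p was 2.0e-05, the smallest that 100000 resamples can give (two-sided, adjusted p = 2.3e-04 over 23 lists), and no list was lower. Heterochronic genes had a median percentile of 75.1 (adjusted permutation p = 0.394), and they passed without replicate 2 and with peaks supported in both replicates (adjusted p over 5 alternatives from 0.0159 to 0.437). The ribosomal call ended with the stronger 4375 peaks (adjusted p over 5 alternatives from 2.1e-04 to 0.249). Only 38 of the 68 bound ribosomal protein genes (55.9%) were the gene nearest to their strongest peak, against 74.8% of all bound protein-coding genes. Peak strength was not recomputed with the nearest start only or without peaks near small RNA genes. Without replicate 2, 4 lists were called stronger, with heterochronic genes and numbered collagens added. Without replicate 1, 2 lists were called weaker, the F-box A and cytochrome P450 genes.

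The word AAAGTGAAA, the core shared by vertebrate Blimp-1 sites, was concentrated at summits and most of all at strong ones. With at most 1 mismatch it lay within 75 bp of 2799 of 8751 summits (32.0%, exact 95% interval 31.0 to 33%), against 19.3% of windows 500 bp to either side (ratio 1.66). The summit alone held it at 2205 peaks and the right flank alone at 1104 (exact binomial p = 4.8e-83). Exact matches stood at 5.42% of summits and 1.13% of flanks (ratio 4.81), among them those of atf-2, W03F8.4, dpy-10, che-14, kin-20 and grh-1. Of the 1750 strongest peaks 47.4% (45 to 49.7%) held the motif, against 26.1% (24.1 to 28.2%) of the 1750 weakest, a difference of 21.3 percentage points (Fisher's exact test, two-sided, p = 4.4e-39). Sites, not samples, are the units of these tests.

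**Figure D3:**
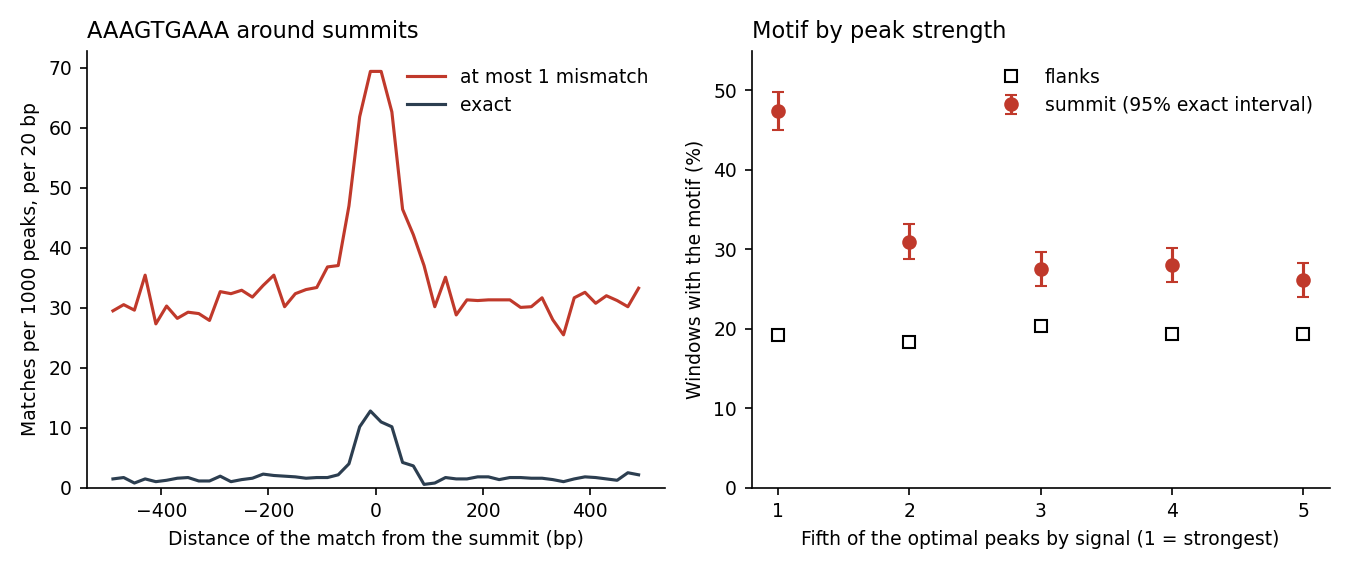
Left, matches to AAAGTGAAA per 1000 optimal peaks in bins of 20 bp by distance from the summit in bp, with at most 1 mismatch and exact. Right, share of summit windows with at most 1 mismatch (%, points with 95% exact intervals) and of flanks (squares) in 5 groups by signal, where the strongest group holds 47.4% and the weakest 26.1%, with flanks between 18.4 and 20.3%.

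Chromosome X held more peaks than its share of genes. It held 1790 of 8751 peaks (20.5%, exact 95% interval 19.6 to 21.3%) and 13.7% of protein-coding genes (ratio 1.5; exact binomial test, two-sided, p = 7.6e-68). Against its 17.7% of genome length the ratio was 1.16 (exact p = 2.1e-11). Among X genes 28.7% were bound, close to the 27.4% of all genes, with the highest shares on III (36.1%) and I (34.1%). Chromosome V held 16.2% of peaks and 25% of genes, and 20.1% of its genes were bound. Peaks stood at 101 per Mb on X, 99.5 on II, 99.4 on III, 91.6 on I, 72.5 on IV and 67.9 on V.

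Around blmp-1 and unc-119, the genes named in the strain's description, peaks were not more numerous than around the median gene. No summit of the optimal list lay within 20 kb of blmp-1 (I 10409302 to 10414773), where the median gene had 3, and 84.3% of protein-coding genes had more. The pooled list and both replicates' own lists held no summit there either. Near unc-119 (III 10902641 to 10908935) lay 3 optimal summits, at 10896014, 10909887 and 10911436, which equals the median of all genes, and none fell in its promoter window. This comparison has no test. It counts summits and not signal, so it cannot show whether extra copies of a region raised the signal there.

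**Figure D4:**
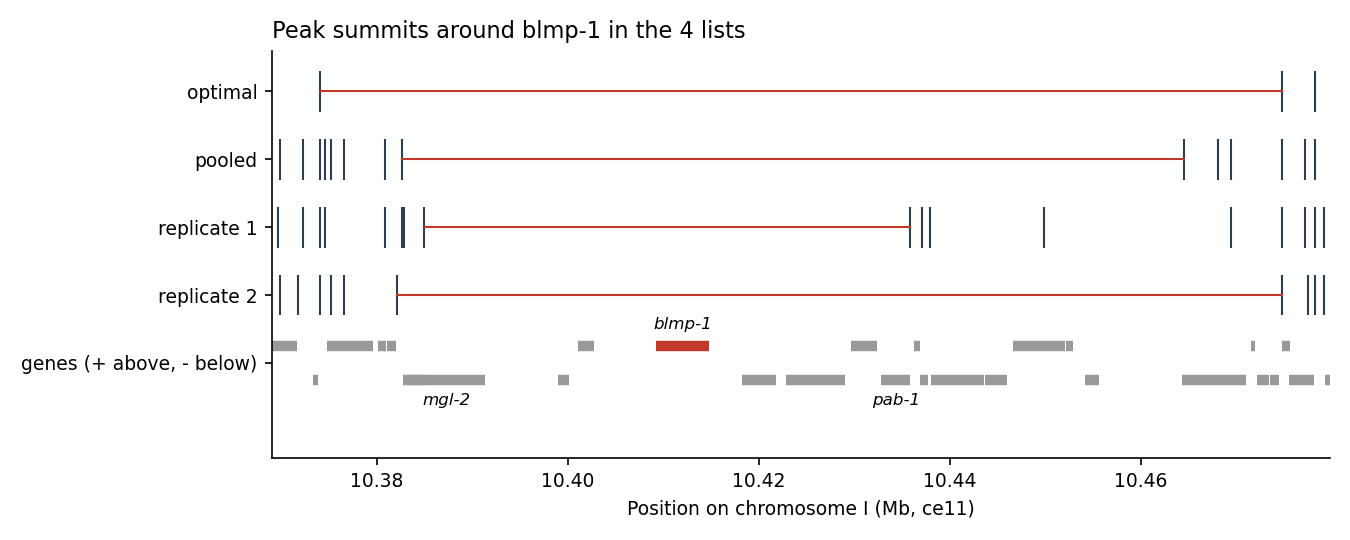
Summits (vertical ticks) of the 4 peak lists and protein-coding genes (bars, plus strand above, minus strand below, blmp-1 in red) around blmp-1 on chromosome I, position in Mb on ce11. Horizontal lines mark the stretch without summits around blmp-1 in each list, 101 kb in the optimal list, 81.8 kb in the pooled list, 50.9 kb in replicate 1 and 92.7 kb in replicate 2.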

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

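The split by replicate support below was chosen after the motif had been seen to thin out with rank below the optimal list, and the other tests in this part were stated before their values were computed.

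Peaks called on both replicates together that fell below the optimal list carried a small excess of words within 1 mismatch of AAAGTGAAA, a signal in data that the comparisons above do not use. Exact matches were not counted at these peaks, so the word itself was not told apart from words 1 base away. Of these 21249 peaks, 23.1% (exact 95% interval 22.5 to 23.6%) held AAAGTGAAA with at most 1 mismatch within 75 bp of the summit, against 19.5% of flanks, and 3 counts, the limit that a count of 0 allows, would be 0.0141%. Shoulders of optimal peaks are argued against as the whole cause, since without peaks within 2000 bp of an optimal summit the ratio of summits to flanks was 1.16 (exact binomial p = 5.6e-13). Base composition is argued against only as far as dinucleotides go: the windows held the motif 1.28 times as often as their dinucleotide shuffles (Fisher's exact test, p = 2.0e-37). The flanks, at 19.5%, also exceeded the 18.1% of the shuffled windows, so this test cannot exclude other features of sequence composition. The share was 25.6% (24.4 to 26.8%) where both replicates' lists held a summit, 22.4% (21.7 to 23.1%) where 1 did and 21.8% (20.4 to 23.2%) where neither did. A candidate explanation is that the discarded peaks mix weak BLMP-1 sites with background, and no biological explanation was tested.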

How the results depend on the processing

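Of 81 values recomputed for the main results, 68 kept their direction and side of the threshold or stayed within their spread, 13 moved and none reversed; no test among them lost its call. With the stronger 4375 peaks, the peak count was 4375, the Spearman's rho between replicates 0.591, the lists called lower in binding 5 and those called stronger in peak strength 1. The first follows from the setting, and the cause of the others was not tested. The overlap of the replicates was 80.7% with any overlap of 1 bp, 64.4% with reciprocal overlap of at least 50% of each interval and 71.9% with the 2187 strongest peaks. The rho was 0.719 with summits within 50 bp and 0.729 with peaks supported in both replicates, where 4 lists were called stronger. With the nearest start only, 5 lists were called lower in binding. The causes were not tested. Without replicate 1 or 2, the lists called stronger ranged from 2 to 4 and those called weaker from 0 to 2. Over single gene lists, 385 of 423 values kept their call, 23 lost it, 15 gained one and no called list reversed. Among those that kept their call, 28 effect sizes of lists called in neither setting changed sign. The shares of peaks near starts (41 to 41.4% without a replicate), the motif ratio (1.64 to 1.66) and the X ratio (1.5 to 1.53) hardly depended on the replicate. Read depth is unknown, so what it limits cannot be given.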

Other observations

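The words found at summits, the comparisons by chromosome and by replicate support, the genes with the most peaks, the split by repeats and by rank-matched peaks, and the tests of genes with exactly as many starts, of a fixed mask and of neighbouring genes as the whole cause were chosen after results had been seen.

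Several words of 7 bases were frequent at summits. Among 8192 words, read on both strands, the 10 with the smallest p at 4172 peaks on I, III and V were tested at 4579 peaks on II, IV and X, and all 10 passed there (exact binomial test, adjusted over 10). Several of the 10 overlap in sequence, such as AGAGAGA with GAGAGAA and AGAGACG with GAGACGC, so they are not 10 independent results. The top word, AGAGAAA, lay at 23.1% of the tested summits and 6.55% of their flanks (adjusted exact p = 2.4e-118), and AGAGAGA at 15.7% and 2.78%. AGAGAAA can lie inside a match to AAAGTGAAA with 1 mismatch, so the counts overlap, but at the 5952 peaks without the motif it still lay at 21.3% of summits (20.3 to 22.4%) and 6.90% of flanks (exact p = 1.1e-118). The word CTGCGTC lay at 7.32% of tested summits and 1.02% of flanks (ratio 7.20, adjusted exact p = 1.5e-58). At the strongest peaks of nuclear hormone receptor genes CTGCGTC stood at 20 of 98 summits (20.4%, exact 95% interval 12.9 to 29.7%), and at those of all bound genes at 10.8% (9.90 to 11.8%), a difference that was not tested.

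The gene with the most peaks in its windows was egl-27, which encodes an MTA1-related chromatin protein, with 11 peaks over 14 transcript starts. It was followed by the phosphatase gene vhp-1 with 7, and by lin-42, the junction gene ajm-1 and the filamin gene fln-2 with 6 each. In all 202 protein-coding genes had 3 or more peaks. A smaller share of X summits (33.4%, 31.2 to 35.6%) than of autosomal ones (42.8%) lay within 500 bp of a start (Fisher's exact test, p = 2.6e-13). Peaks beyond 500 bp stood at 67.3 per Mb on X, 59.5 on II, 58.0 on III, 50.8 on I, 43.5 on IV and 35.6 on V. Those within 500 bp stood at 33.7 per Mb on X, 41.4 on III, 40.9 on I, 40.1 on II, 32.3 on V and 29.0 on IV. X holds 13.7% of protein-coding genes on 17.7% of the length. No expectation from shifts was computed per chromosome, so the share of X positions near a start by chance is not known. Optimal peaks matched in replicate 2 only held the motif at 25.6% (23.3 to 27.9%), those matched in replicate 1 only at 31.0% (27.5 to 34.8%) and those matched in both at 33.6% (32.5 to 34.8%). Their median signals were 88.8, 73.9 and 185 in that order. The motif was more frequent at stronger peaks, and these shares were not adjusted for strength.

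No peak was listed around blmp-1, the gene carried by the transgene, over 81.8 kb of the pooled list, where only 17 of 29994 spacings were as long. Chance spacing in a stretch with few starts is argued against, since of 16962 genes with at least as many starts within 20 kb 702 (4.14%) had no pooled summit there, and of 1634 with exactly as many 29 (1.77%, exact 95% interval 1.19 to 2.54%, over windows that overlap). Repeated sequence stays open: 12% of words of 31 bases within 20 kb of blmp-1 recur in the genome, above the median of 5.33% and below the 95th percentile of 23.3% of genes with summits, and of 3458 genes at least as rich in starts and repeats 384 (11.1%) were equally empty, so chance together with repeats stays open too. A single fixed mask over the whole pooled stretch is argued against by 6 summits of replicate 1 inside it, one of them in the 5′ UTR of pab-1 at I 10435873, but not for the 50.9 kb that every list leaves empty. A higher control signal from extra copies of the region could also hide peaks and was not tested, since the control was not analysed here.

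Ribosomal protein and proteasome genes were bound at 68 of 77 and 28 of 33, and no motif excess over flanks was detected at their peaks. At the 93 strongest peaks of these genes AAAGTGAAA stood at 17.2% of summits (exact 95% interval 10.2 to 26.4%), 1.28 times its share in their flanks (exact binomial p = 0.678), and rank-matched peaks at other starts held it at 29.6% (20.4 to 38.7% over 10000 draws, one-sided permutation p = 0.00490). Numbered collagens held it at 50% of 62 peaks against 15.3% of flanks (exact p = 5.9e-05). Nuclear hormone receptors (23.5% and 15.8%, exact p = 0.200) and the 13 peaks of heterochronic genes (46.2% and 30.8%, exact p = 1.00) showed no excess past the threshold. These tests rest on few peaks and cannot show that an excess is absent, and neither list was compared with rank-matched peaks. Whether the low motif share is particular to ribosomal protein and proteasome genes thus stays open. The flanks of ribosomal protein and proteasome peaks held the motif at 13.4%, against 18.6% for the strongest peaks of all bound protein-coding genes. The rank-matched comparison used summits alone, so it cannot tell a low share at summits from a low share around them. The low motif share at ribosomal protein and proteasome peaks could reflect binding at open promoters without the motif. That is a hypothesis found and tested on the same data, in which openness was not measured. Peaks of neighbouring genes may add to the count, since 58.3% of bound members were the gene nearest to their strongest peak against 75.1% of other bound genes (Fisher's exact test, p = 3.4e-04). As the whole of it they are argued against with the nearest start only, by a log2 odds ratio of 1.70 for ribosomal protein genes (Fisher's exact test, adjusted p = 2.0e-06) and 1.84 for proteasome subunits (adjusted p = 7.9e-04). In that setting a summit counted up to 3000 bp from the start on either side, so reach and assignment changed together.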
